A study of Mus musculus with 2 samples.

How the data were processed

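Single-cell RNA sequencing of Hepa1-6 tumours from mice was analysed in 2 libraries, 1 from a control and 1 from mice given CD147-LYTACs. Per the labels, the treated mice received 40 mg/kg every 3 days for 4 doses and the tumours were taken on day 12. The labels leave open whether the route was intraperitoneal or intravenous, and do not state how many tumours went into each library. CD45-negative and CD45-positive cells were separated by flow cytometry and recombined at 1 part to 3 parts, so immune cells were planned to make up 75% of the input. Libraries were made on the 10x Genomics Chromium platform and sequenced on an Illumina NextSeq. Groups were taken from the treatment label of each sample.

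The deposited matrices hold raw UMI counts per gene and cell barcode, as whole numbers without normalization. Per the submitters' processing notes they were made with Cell Ranger 3.0.2 on mm10, whereas the software named per the file headers is Cell Ranger 7.1.0, and the annotation release is not given in the sources used here. The matrices list 32285 genes, of which 32235 identifiers (99.8%) occur in GENCODE release M21, which was used for gene positions on GRCm38 (mm10). The deposited barcodes had been filtered to at least 500 UMIs in both libraries, as the counts show. The control library held 8150 barcodes and 143495332 UMIs, and the treated library held 9219 barcodes and 149812326 UMIs.

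Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs, which left 7091 control barcodes (87.0%) and 8176 treated barcodes (88.7%). Scrublet as built into scanpy scored doublets in each library. Its automatic threshold marked only 1 control barcode and 132 treated barcodes and so had not worked in the control library. The barcodes with the highest scores were removed instead, at a rate of 0.8% per 1000 barcodes, which took out 402 control and 535 treated barcodes. The remaining 6689 and 7641 cells were clustered together without batch correction, from the log of counts per 10000, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor segment genes, Xist and Y-linked genes were kept out of the variable genes.

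Clusters were named "X-like" from marker lists fixed before the data were examined. A marker counted as detected where at least 10% of the cells held it with a log2 fold above 1 over all other cells, and a name needed at least 3 detected markers. A cluster stayed unnamed where its top 10 genes held more markers of another class than of its own, or where its UMI count was low and none of its markers was among those genes. T or NK-like cells and monocyte or macrophage-like cells were clustered again and their sub-clusters were named from second-level markers, with Cd8a above 3 times Cd4 for the CD8 T-like name. By leading genes within the class, macrophage-like and monocyte-like names were compared only with each other. Markers of other lineages could remove such a name only through the 10 leading genes against all other cells. Sub-clusters in which at least 25% of the markers of another lineage were detected, and at least 5 of them, were kept out of every class as mixed cells, and each class was clustered again until none was left. These thresholds, the repetition and the checks on sub-cluster names were set after seeing the data. The names of the macrophage-like and monocyte-like sub-clusters rest on a choice made after seeing the outcome of another: an earlier version judged them by their leading genes against all other cells and left the most populous monocyte-like sub-cluster unnamed, and the version used judged them by their leading genes within the class. Values from the earlier version are given with the other alternatives. Mixed cells made up 2.47% of clustered control cells and 7.32% of clustered treated cells, and unnamed clusters 5.62% and 2.88%. This left 6148 named control cells and 6862 named treated cells.

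With 1 library per group there was no test between groups, and no p-value or standard error was made from cells. Shares are given with exact Clopper-Pearson 95% intervals. UMI counts were summed per library and cell type and expressed as CPM of the sum, with exact Poisson 95% intervals, and log2 ratios (treated over control) have exact conditional binomial 95% intervals. All of these intervals cover counting error only, not differences between mice, tumours or library preparations. In a ratio of counts, a zero was taken to allow up to 3 counts. Expression was compared in the 10 cell types with at least 100 cells in each library.

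Genes were named by a rule fixed before the data were examined. Among genes with at least 100 UMIs over both libraries in a cell type, at least 50 CPM in the higher library, an interval excluding no difference and a difference of at least 1.5-fold, the 10 with the greatest and the 10 with the smallest ratio were taken. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor segment genes, Xist, Y-linked genes and models named only by number were left out of this ranking. Genes below 20% of their highest level in another cell type of the same library were also left out, since free RNA could account for them. Only cell types with at least 100 cells in that library were compared. Free RNA from rarer types, such as B-like cells, was therefore not checked. Added to these by the same rule were Bsg, Slc16a1, Slc16a3, Ldha and Ldhb where they had at least 30 UMIs, the genes listed for shares of cells with a UMI, and the 4 members of each described list with the greatest absolute log2 ratio. Some of the named genes are not described, and some items are not reported here. For 28 fixed gene lists, the median log2 ratio of members with at least 30 UMIs was given with a 95% interval from 1000 Poisson resamples of the counts, with the number of members at least 1.5-fold higher or lower, and with its percentile among 10000 random lists of the same size, drawn from the 100 genes nearest in mean expression to each member. These percentiles describe these libraries and are not tests.

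For shares of cells with at least 1 UMI of a gene, each cell was thinned to 1000 UMIs and shallower cells were left out. This took out 10 control and 5 treated hepatoma-like cells, 10 and 3 CD8 T-like cells, 20 and 11 T or NK-like cells, 18 and 69 monocyte or macrophage-like cells, 9 and 37 macrophage-like cells, and 11 and 58 neutrophil-like cells.

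The calculations were tested on simulated Poisson counts drawn from the real means and library sizes. The intervals assume such counts, so their coverage checks the calculation and does not cover spread between cells. Intervals held the true ratio for 95.0% of 13489 genes in the hepatoma-like simulation, 95.4% of 9824 in CD8 T-like, 95.6% of 5417 in monocyte or macrophage-like and 95.7% of 3949 in neutrophil-like cells. All simulated 2-fold and 4-fold changes above 50 CPM met the naming rule: 21 and 23 genes in hepatoma-like, 29 and 38 in CD8 T-like, 40 and 56 in monocyte or macrophage-like and 34 and 55 in neutrophil-like cells. Of the unchanged genes, 0 of 13294, 0 of 9629, 6 of 5237 and 44 of 3778 met it, so in neutrophil-like cells, with few control UMIs, counting error alone can meet the rule.

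Alternatives fixed before the data were examined covered a looser filter (300 UMIs, 200 genes, 25% mitochondrial) and a stricter one (1000 UMIs, 500 genes, 10%), no doublet removal, a doublet rate of 1.6%, Leiden resolutions of 0.5 and 2, libraries clustered separately, median-of-ratios scaling, CPM without mitochondrial, ribosomal and haemoglobin genes, means over cells, other UMI minima for list members, thinning to 500 or 2000 UMIs or none, and clusters with over 90% of their cells from 1 library left out. After seeing the data, 6 more were added: mixed and low-UMI cells put back for shares, the same for monocyte or macrophage-like expression, cells above 3 times the median UMIs of their type left out, all sub-clusters positive for Cd8a counted as CD8 T-like, the other naming of macrophage-like and monocyte-like sub-clusters, and no name for those with more leading markers of another lineage.

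Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.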

Results

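Tumours grown from Hepa1-6, a mouse hepatoma cell line, were profiled by droplet single-cell RNA sequencing in a control group and after treatment with CD147-LYTACs. Lysosome-targeting chimaeras (LYTACs) bind a protein at the cell surface and a receptor that shuttles to the lysosome, so that the bound protein is degraded there. CD147, also called basigin and encoded by Bsg, is a surface glycoprotein that escorts the lactate transporters MCT1 (Slc16a1) and MCT4 (Slc16a3) to the plasma membrane. The comparison addresses lactate metabolism of the tumour cells and the immune cells in the tumour. Each group was 1 library, so no difference between them has a replicate check, and the intervals given cover counting error only. The control library held 8150 barcodes with 143495332 UMIs, a median of 6731.5 UMIs and 2516 genes per barcode. The treated library held 9219 barcodes with 149812326 UMIs, a median of 5953 UMIs and 2281 genes. After filtering, 6148 control cells and 6862 treated cells had a named type. Immune cells made up 69.4% of named control cells and 70.2% of named treated cells, against the 75% planned when sorted CD45-negative and CD45-positive cells were recombined. Cell shares were therefore taken within the immune cells and within the non-immune cells, never across the sort.

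Neutrophil-like cells made up 29.1% (95% interval 27.8 to 30.4) of 4818 named immune cells in the treated library and 3.96% (3.39 to 4.59) of 4268 in the control library, a ratio of 7.35. Monocyte or macrophage-like cells were also more frequent, at 13.5% (12.5 to 14.5) against 6.42% (5.70 to 7.20), a ratio of 2.10. T or NK-like cells were less frequent, at 53.6% (52.2 to 55.0) in the treated library against 84.7% (83.5 to 85.7) in the control library. Conventional dendritic-like cells made up 2.12% against 3.05% and B-like cells 0.643% against 1.05%. Plasmacytoid dendritic-like cells (0.291% against 0.328%) and mast or basophil-like cells (0.747% against 0.539%) were rare in both. With neutrophil-like cells left out of the total, T or NK-like cells made up 75.6% of treated and 88.1% of control immune cells, and monocyte or macrophage-like cells 19.03% and 6.68%. On that total, conventional dendritic-like cells made up 2.99% and 3.17% and B-like cells 0.907% and 1.098%. Plasmacytoid dendritic-like cells turned direction there, at 0.410% and 0.342%. Among non-immune cells, 98.0% of treated and 98.8% of control cells were hepatoma-like, and the remainder were fibroblast or mural-like (2.01% and 1.22%). The effect of sorting on these shares was not tested.

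**Figure D1:**
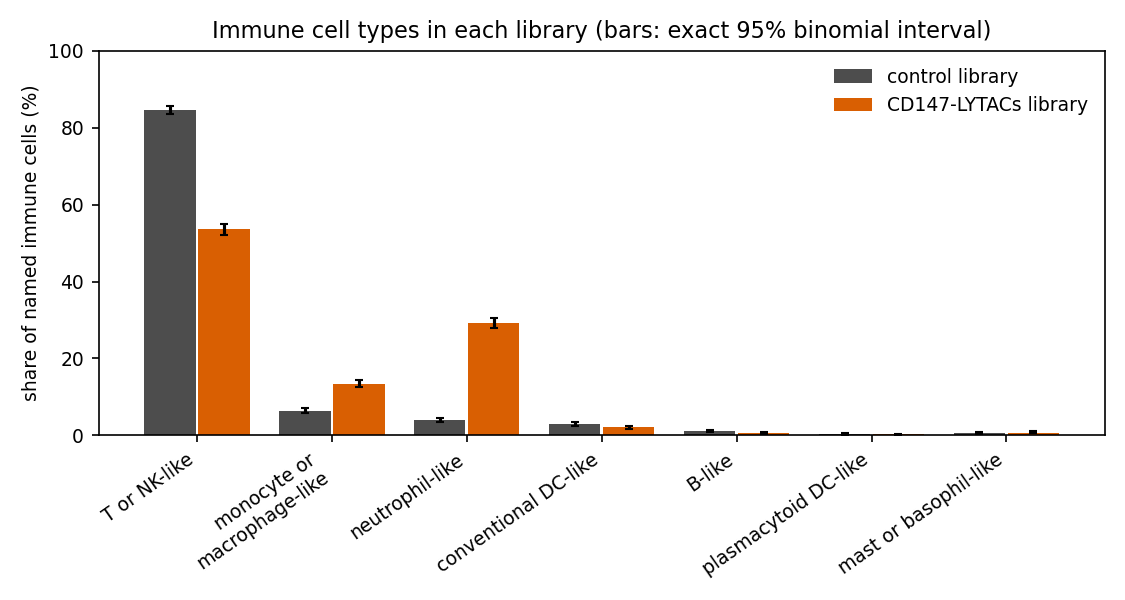
Share of named immune cells (%) by cell type in the control library (grey, 4268 cells) and the CD147-LYTACs library (orange, 4818 cells), with exact 95% binomial intervals as error bars. Neutrophil-like cells stood at 3.96% and 29.1%, and T or NK-like cells at 84.7% and 53.6%.

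Within T or NK-like cells, CD8 T-like cells made up 55.6% (53.6 to 57.5) of 2583 treated and 57.7% (56.1 to 59.3) of 3613 control cells, and regulatory T-like cells 4.22% and 4.21%. Conventional CD4 T-like cells made up 7.70% against 9.63% and NK-like cells 5.15% against 3.02%, and gamma-delta T or ILC-like cells were at 0.581% and 0.471%. Sub-clusters positive for Cd8a that stayed unnamed held a further 22.8% of treated and 21.8% of control cells. The largest of them, sub-cluster 1 (312 treated and 476 control cells), had S1pr1, Lef1 and Tcf7 among its leading genes. CD8 T-like values below leave these cells out. With the libraries clustered separately, the ratio of NK-like shares was 0.393 and that of CD8 T-like shares 1.15. Both directions depended on the clustering. Within monocyte or macrophage-like cells, macrophage-like cells made up 47.2% (43.3 to 51.2) of 650 treated and 21.9% (17.1 to 27.3) of 274 control cells. Monocyte-like cells made up 36.3% of treated cells and 50% (137 of 274) of control cells, and unnamed sub-clusters 16.5% and 28.1%. Of the monocyte-like cells, 96 treated and 2 control cells lay in sub-cluster 4. Its 10 leading genes within the class held no monocyte marker but the neutrophil genes Lcn2, S100a8, S100a9 and Cxcl3. Its 10 leading genes against all cells held the monocyte markers Vcan and F13a1, the macrophage marker Arg1 and no neutrophil marker. The name of these cells is uncertain. Sub-clusters 4 and 5 held more markers of another lineage among their leading genes within the class. With both left unnamed, monocyte-like cells made up 21.5% and 49.3%, a ratio of 0.437. Macrophage-like cells then made up 42.8% and 12.4%, a ratio of 3.45. Sub-cluster 5 had 19 detected macrophage markers and held C1qa and Mmp12 among its leading genes against all cells, so this variant may leave out macrophages. The ratio of macrophage-like shares was 2.16 and ranged from 1.17 with a looser barcode filter to 3.76 at a Leiden resolution of 0.5. The ratio of monocyte-like shares was 0.726 and turned to 1.23 with a stricter filter and to 1.104 with sub-clusters named by fold against all cells.

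Hepatoma-like cells of both libraries held nearly the same levels of Bsg and of the lactate genes. Bsg (ENSMUSG00000023175), a protein-coding gene at chromosome 10, 79704491 to 79711969 (GRCm38/mm10, plus strand), was at 1013 CPM in the treated and 992 CPM in the control library, a log2 ratio of 0.03 (0.02 to 0.04). LYTACs act on the protein, so the Bsg transcript does not measure the degradation of CD147. Slc16a1 (chromosome 3, 104638668 to 104658462) was at 38.4 and 36.5 CPM, a log2 ratio of 0.07 (0.00 to 0.14). Ldha, the lactate dehydrogenase subunit that favours lactate formation (chromosome 7, 46841475 to 46855627), was at 980.2 and 954.9 CPM, a log2 ratio of 0.04 (0.02 to 0.05). Slc16a3 (chromosome 11, 120948480 to 120960868) was close to absent, at 0.363 and 0.236 CPM, and a difference was not detectable at this depth (log2 ratio 0.62, -0.19 to 1.46, or -0.90 as a mean over cells). Among hepatoma-like cells thinned to 1000 UMIs, 56.0% of cells in each library held a UMI of Bsg, against 11.6% of treated and 10.4% of control T or NK-like cells, which also express it. For Ldha the shares were 56.8% and 55.6% and for Slc16a1 4.10% and 3.63%. Before thinning, Bsg was seen in 98.2% of treated and 97.3% of control hepatoma-like cells, Ldha in 98.8% and 98.0%, and Slc16a1 in 67.6% and 68.0%. Median depths were 43764 and 46682 UMIs in hepatoma-like cells and 6098 and 6159 in T or NK-like cells.

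**Figure D2:**
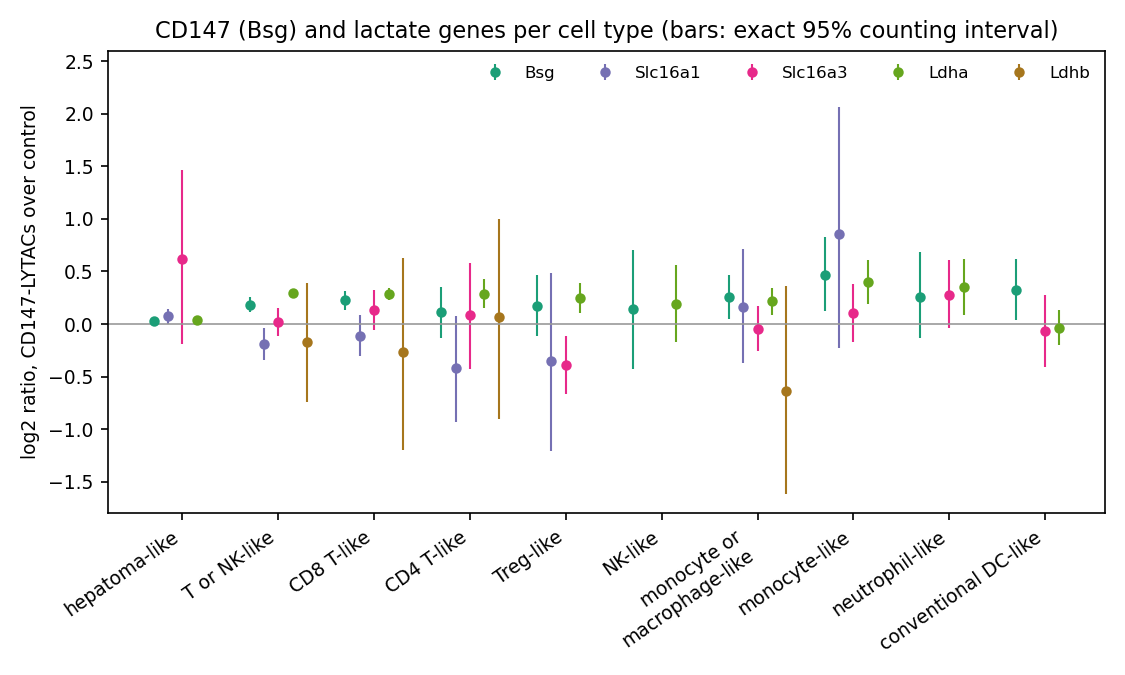
Log2 ratio of CPM (CD147-LYTACs library over control library) for Bsg, Slc16a1, Slc16a3, Ldha and Ldhb in each of 10 cell types, with exact 95% counting intervals as lines and genes under 30 UMIs in a type not drawn. In hepatoma-like cells Bsg lay at 0.03 and Ldha at 0.04, while in T or NK-like cells Ldha lay at 0.29.

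In hepatoma-like cells 4 genes met the naming rule, which leaves out genes under 50 CPM or at the level of free RNA, and all were lower in the treated library: Camk1d, a calcium-dependent kinase (1039 against 2017 CPM, log2 ratio -0.96), Cdk8, a Mediator kinase (271 against 479, -0.82), Cmss1, a ribosomal small subunit factor (1179 against 2008, -0.77), and Lars2, the mitochondrial leucyl-tRNA synthetase (427 against 643, -0.59, or -0.31 as a mean over cells). The same 4 genes were lower in each of the 9 immune types and subsets measured, so these values were not specific to tumour cells.

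The list of CD147, lactate transport and lactate metabolism genes had a median log2 ratio of 0.09 (0.05 to 0.14) over 16 members in hepatoma-like cells, at the 99.6th percentile of matched random lists. Of its members 1 was at least 1.5-fold higher (Slc16a3, near absent) and 1 lower (Emb). Emb, which encodes embigin, another chaperone of lactate transporters, was at 1.32 against 2.34 CPM (-0.83), a level that free RNA from T cells could give. Mpc2, a subunit of the mitochondrial pyruvate carrier, was at 135 against 116 CPM (0.22). Genes of oxidative phosphorylation were slightly higher together, with a median of 0.09 (0.08 to 0.10) over 53 members at the 99.99th percentile and none past 1.5-fold, as in Sdhb (0.22) and Ndufs3 (0.21). Proliferation genes had a median of 0.07 (0.05 to 0.10) over 36 members at the 99.9th percentile, with Tyms at 0.32, Birc5 at 0.28 and Rrm2 at 0.27. Lysosome and endocytic receptor genes had a median of 0.05 (0.02 to 0.06) over 36 members at the 98.8th percentile, with the protease Ctsl at 0.28 and Igf2r, a receptor that carries cargo to lysosomes, at -0.20. Glycolysis genes lay at 0.01 (-0.02 to 0.03) over 19 members at the 50.7th percentile, with the regulatory enzyme Pfkfb3 at 0.42 (4.40% of its level in another cell type) and Pfkp at -0.14. Hypoxia response genes lay at -0.06 (-0.08 to -0.04) over 22 members at the 6.94th percentile, with Ier3 at 0.58 (12.1% of another type) and Vegfa, the angiogenic growth factor, at -0.26. MHC class I presentation genes lay at 0.01 (0.00 to 0.03) over 22 members at the 54.2th percentile, with H2-D1 at 0.15, Psmb8 at 0.14 and Nlrc5 at -0.16. Interferon-gamma response genes lay at -0.05 (-0.07 to -0.02) over 36 members at the 5.42th percentile, and Cxcl9, a T cell attracting chemokine, stood at 76.3 against 64.1 CPM (0.25).

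Type I interferon response genes were lower in treated hepatoma-like cells, with a median of -0.12 (-0.18 to -0.09) over 35 members at the 0.20th percentile and 7 members at least 1.5-fold lower. Ifit1 was at 2.42 against 7.87 CPM (-1.70), Ifit3 at 0.425 against 1.37 (-1.69), Ifit3b at 1.45 against 3.34 (-1.20) and Rsad2, an antiviral enzyme, at 6.47 against 12.6 (-0.96). Ifit1, Ifit3 and Rsad2 stood at 8.45%, 8.99% and 2.12% of their level in another cell type. Cd3e, a T cell gene, held a smaller share, at 0.782 CPM in control hepatoma-like cells against 286 in control T or NK-like cells. Whether free RNA gave the counts of these 3 interferon genes was not tested. As a mean over cells, Ifit3 was at -0.65. Lists of myeloid genes were higher in treated hepatoma-like cells, at 0.33 for tumour neutrophil and suppressive myeloid genes (12 of 29 members at least 1.5-fold higher) and 0.20 for chemokines (7 of 23). Cxcl2, a neutrophil-attracting chemokine on both lists, was at 65.5 against 26.8 CPM, or 0.101% of its level in another cell type. Free RNA could give that level.

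**Figure D3:**
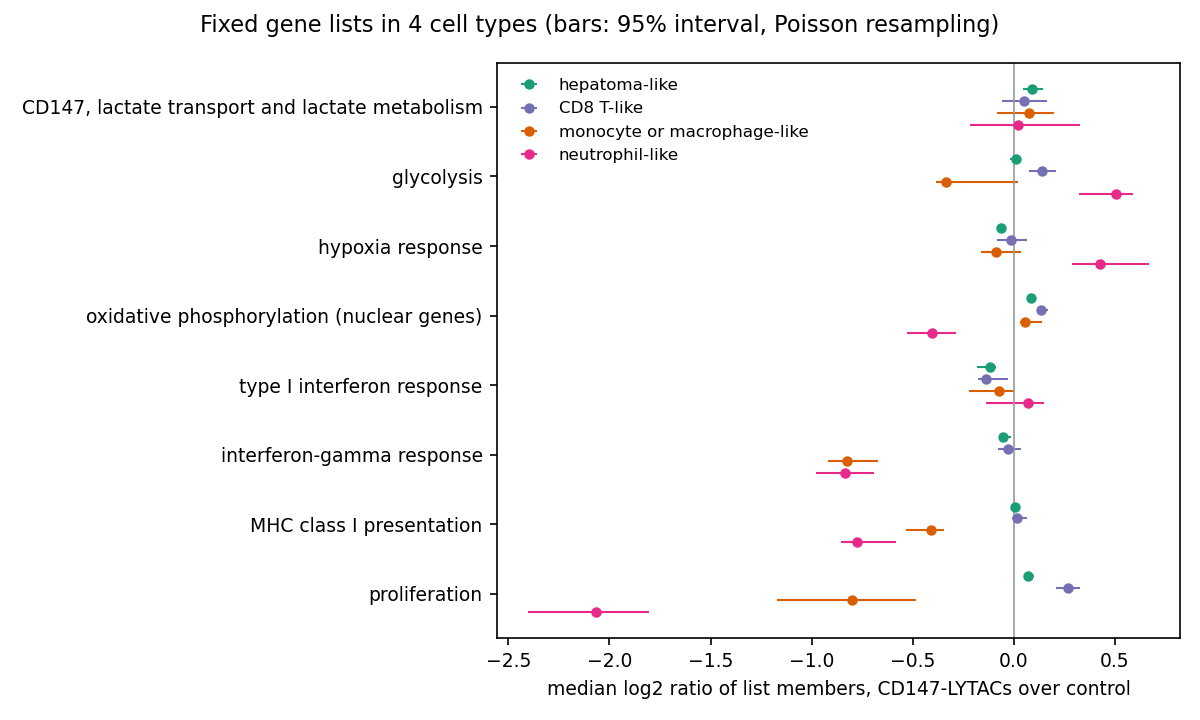
Median log2 ratio (CD147-LYTACs library over control library) of 8 fixed gene lists in hepatoma-like, CD8 T-like, monocyte or macrophage-like and neutrophil-like cells, with 95% intervals from Poisson resampling of the counts as lines. Hepatoma-like medians lay between -0.12 and 0.09, while the interferon-gamma list lay at -0.82 in monocyte or macrophage-like and -0.83 in neutrophil-like cells.

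T or NK-like cells expressed Bsg at 138 CPM in the treated and 121 CPM in the control library (log2 ratio 0.19, 0.11 to 0.26) and Ldha at 415 and 339 CPM (0.29, 0.25 to 0.33). Their Bsg level was 13.6% of that in hepatoma-like cells, and Krt8, a tumour cell keratin checked afterwards, was at 20.7 and 21.6 CPM against 1802 and 1722. Emb was lower, at 884 against 1161 CPM (-0.39), and Mpc2 was at 87.7 against 74.8 CPM (0.23). The lactate list had a median of 0.02 (-0.04 to 0.12) over 14 members at the 83.2th percentile, none past 1.5-fold. Slc16a1 was at 29.1 against 33.1 CPM (-0.19) and Slc16a3 at 39.0 against 38.5 CPM (0.02). After thinning, 11.6% of treated and 10.4% of control T or NK-like cells held a UMI of Bsg (51.6% and 47.7% before thinning), and 27.1% and 23.7% one of Ldha (76.5% and 71.9%). Foxp3, the regulatory T cell factor, was seen in 1.05% and 1.25% of T or NK-like cells (3.87% and 3.68% unthinned) and in 0 of 1998 and 0 of 1847 hepatoma-like cells. Ctla4, an inhibitory receptor, was seen in 31.1% and 29.1% (72.7% and 72.2%), against 1.30% and 1.68% of hepatoma-like cells.

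CD8 T-like cells of the treated library held more transcripts of the cell cycle and somewhat more of effector molecules, while the inhibitory receptor list lay near 0. Of the 10 genes with the greatest ratios, 5 were histone genes: Hist1h2an (88.5 against 49.0 CPM, log2 ratio 0.85), Hist1h2ae (0.84), Hist1h1b (0.78), Hist1h2ab (0.72) and Hist1h4d (0.71). The others were the microtubule regulator Stmn1 (292 against 176, 0.73), Cks1b, a partner of cyclin-dependent kinases (0.72), the chromatin protein Hmgn2 (0.68), the mitotic protein Birc5 (0.64) and the sulfotransferase Sult2b1 (0.74). The 10 with the smallest ratios were Cdk8 (289 against 636, -1.14), Dlg2 (-0.87), Mpp7 (-0.74), Pou2f2 (-0.70), Sgms1 (-0.70) and Camk1d (-0.69), followed by Lef1, a factor of naive and memory T cells (39.8 against 63.6, -0.68), Slco3a1 (-0.67), Dscam (-0.67) and Csf1, the macrophage growth factor (111 against 169.9, -0.62). Among planned genes, Ifng was at 309.9 against 248 CPM (0.32), Gzmb, which encodes granzyme B, at 639 against 512 (0.32), Tox, a factor of exhausted T cells, at 413 against 337 (0.29), and Mki67, a proliferation marker, at 266 against 197 (0.43). Pdcd1, which encodes PD-1, was at 355 against 339 CPM (0.06), Havcr2 (TIM-3) at 304 against 311 (-0.03), Lag3 at 103 against 113 (-0.13), Tigit at 30.7 against 33.7 (-0.14) and Prf1, which encodes perforin, at 177 against 175 (0.01).

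The proliferation list had a median of 0.27 (0.21 to 0.33) over 36 members in CD8 T-like cells, at the 100th percentile, but -0.02 with the libraries clustered separately. In the main setting 4 members were at least 1.5-fold higher: Stmn1, Tk1 (0.68), Birc5 and Aurkb (0.63). Cytotoxic effector genes had a median of 0.11 (0.06 to 0.19) over 26 members at the 99.9th percentile, with 2 members higher, Gzma (145 against 85.3 CPM, 0.76) and Gzmc (0.75), and the terminal effector factor Zeb2 lower (555 against 817, -0.56). Gzma stood at 5.70% and Gzmc at 16.1% of their level in another cell type, so free RNA could add to both. Genes of glycolysis (0.14, 0.08 to 0.21, 18 members, 99.9th percentile) and oxidative phosphorylation (0.14, 0.12 to 0.17, 53 members, 100th percentile) were slightly higher together, with no member past 1.5-fold, as in Tpi1 (0.40), Eno1 (0.30), Ndufv1 (0.45) and Ndufb5 (0.41). Inhibitory receptor and exhaustion genes had a median of 0.01 (-0.03 to 0.06) over 24 members at the 86.1th percentile, with Cd160 higher (0.81), Tox2 lower (-1.30, at 1.40 against 3.44 CPM, but -0.52 as a mean over cells) and Eomes at 0.40. Naive and memory genes had a median of -0.10 (-0.21 to -0.03) over 16 members at the 26.0th percentile, but 0.07 at a doublet rate of 1.6%. Of the members, 2 were at least 1.5-fold lower, among them Lef1, and Satb1 was at 493 against 711 CPM (-0.53). These values leave out the unnamed Cd8a-positive sub-cluster with Lef1 and Tcf7 among its leading genes.

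Thinned to 1000 UMIs, 24.0% (21.8 to 26.3) of treated and 20.1% (18.4 to 21.9) of control CD8 T-like cells held a UMI of Ifng, and 35.8% (33.3 to 38.3) and 30.8% (28.8 to 32.8) one of Gzmb. Tox was seen in 26.7% (24.4 to 29.0) and 20.4% (18.7 to 22.2). Pdcd1 was seen in 29.1% and 26.7%, Havcr2 in 25.6% and 26.6%, Lag3 in 9.29% and 11.2%, Tigit, another inhibitory receptor, in 3.00% (2.18 to 4.02) and 3.95% (3.16 to 4.88), and Prf1 in 14.6% of cells in each library. Unthinned values were 64.9% and 59.7% for Ifng, 72.3% and 65.0% for Gzmb, 62.4% and 52.3% for Tox, 80.1% and 77.5% for Pdcd1, 72.8% and 69.4% for Havcr2, 49.1% in each library for Lag3, 20.6% and 21.8% for Tigit and 56.0% and 53.8% for Prf1. In thinned hepatoma-like cells, which should lack them, these genes were seen in at most 0.325% of cells, except Tox at 2.95% and 2.87%. Mki67 was seen in 11.7% (10.0 to 13.4) of treated and 6.99% (5.93 to 8.17) of control CD8 T-like cells (24.2% and 16.5% unthinned), with no reference type, since hepatoma-like cells also divide (7.06% and 7.80%). Tcf7, a factor of stem-like T cells, was seen in 2.09% and 2.12% (7.11% and 8.11% unthinned), again with no reference type, since hepatoma-like cells also held it (3.35% and 3.52%, or 69.8% and 69.5% unthinned). The unnamed Cd8a-positive sub-cluster with Tcf7 among its leading genes is not part of these Tcf7 shares. Median depths were 6694 UMIs in treated and 6677.5 in control CD8 T-like cells.

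**Figure D4:**
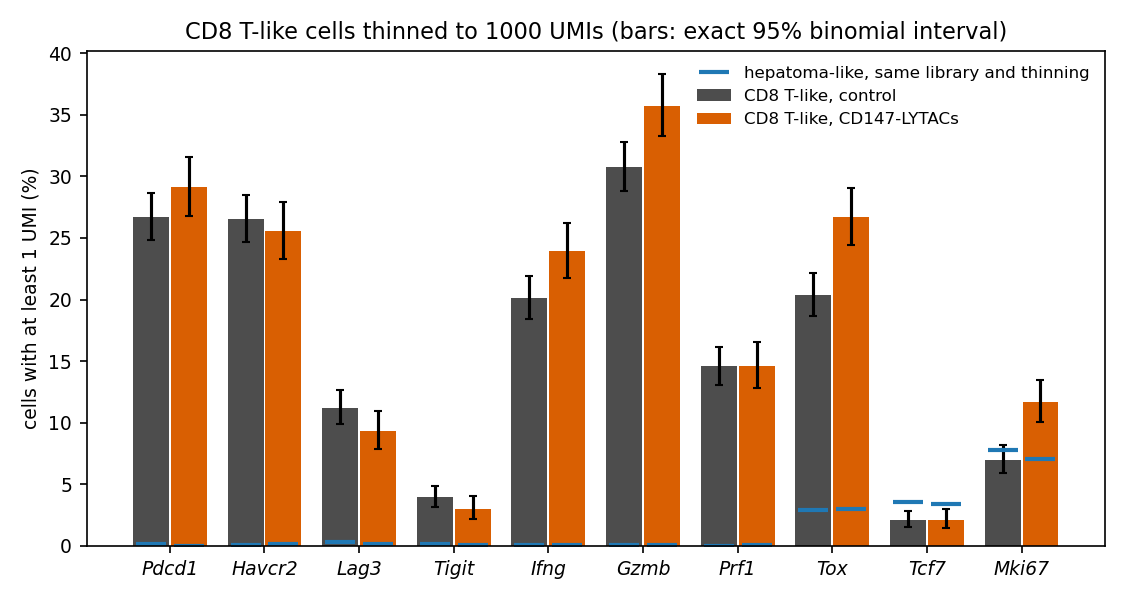
Share of CD8 T-like cells (%) with at least 1 UMI of each gene after thinning to 1000 UMIs, in the control library (grey, 2074 cells) and the CD147-LYTACs library (orange, 1432 cells), with exact 95% binomial intervals as error bars and the share in hepatoma-like cells of the same library as a blue line. Gzmb stood at 30.8% and 35.8% and Tox at 20.4% and 26.7%. Hepatoma-like cells are no reference for Tcf7, which they also held.

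The largest CD8 T-like sub-cluster was number 0 in the control library (777 of 2084 cells, against 317 of 1435 treated cells) and number 3 in the treated library (389 against 324 cells). Sub-cluster 4, led by histone genes and Mki67, held 261 treated and 217 control cells, so the class also differed in its share of cycling cells. With the libraries clustered separately, the proliferation list in CD8 T-like cells was at -0.02, Mki67 at 0.02, Birc5 at 0.20, Aurkb at 0.24, Tk1 at 0.36, Stmn1 at 0.40 and Gzmc at -0.09. These differences depended on which cells carried the name.

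Monocyte or macrophage-like cells showed wide differences. In the treated library they held more of chemokine genes and of single genes such as Spp1 and Arg1, and less of interferon-gamma response and antigen presentation genes. The genes with the greatest ratios were Npy, a neuropeptide (74.7 against 0.630 CPM, log2 ratio 6.89, from 1 control UMI, 4.40 to 12.20), the collagenase Mmp8 (4.11), Spp1, which encodes osteopontin (1706 against 122, 3.81), the platelet factor Pf4 (1403 against 137, 3.36) and the acute-phase gene Saa3 (585 against 60.5, 3.27). They also included the chemokine Cxcl3 (1217 against 175, 2.80), Arg1, the arginine-degrading enzyme (1137 against 174, 2.70), the cathepsin Ctsk (2.62), the chitinase-like Chil3 (259.5 against 44.7, 2.54) and Fn1, which encodes fibronectin (283 against 50.4, 2.49). Those with the smallest were Il12b, the shared subunit of IL-12 and IL-23 (3.13 against 60.5, -4.27), Lyz1 (-2.61), the interferon-induced GTPase Gbp2b (-2.56), Ly6i (36.9 against 175, -2.25) and Retnla (-2.13). They also included Cxcl9 (235 against 884, -1.91), the nuclear receptor Pparg (-1.91), Plaat3 (-1.87), Heg1 (-1.83) and Nod1 (-1.77). Several of these genes, among them Spp1, Pf4, Arg1 and Cxcl9, are also among the markers that name macrophage-like sub-clusters.

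Interferon-gamma response genes had a median log2 ratio of -0.82 (-0.92 to -0.67) over 34 members in monocyte or macrophage-like cells, at the 0th percentile, with 21 members at least 1.5-fold lower and 1 higher, as in Gm4951 (49.7 against 190.2 CPM, -1.94). MHC class II presentation genes had a median of -1.18 (-1.22 to -1.13) over 10 members at the 0th percentile, with 8 lower, among them Ciita, the class II transactivator (36.0 against 108, -1.59), H2-Eb1 (1313 against 3102, -1.24) and H2-Ab1 (1555 against 3657, -1.23). MHC class I genes had a median of -0.41 (-0.53 to -0.35) over 22 members at the 0.01th percentile, with 9 lower, as in H2-Q6 (-0.93) and Tap2 (-0.81). Pro-inflammatory macrophage genes had a median of -0.38 (-0.45 to -0.24) over 22 members at the 0.02th percentile, with 8 lower and 4 higher, the latter including Il23a (2.69, from 3 control UMIs, 1.04 to 5.03, at 8.48% of its level in another cell type). Chemokine genes had a median of 0.75 (0.51 to 0.92) over 20 members at the 100th percentile, with 11 higher and 5 lower, as in Ccl2, which attracts monocytes (932 against 180.1, 2.37), and Cxcl1, which attracts neutrophils (889 against 207, 2.10). Lysosome and endocytic receptor genes had a median of 0.29 (0.25 to 0.38) over 35 members at the 100th percentile, with 6 higher and none lower, as in Ctsl (1304 against 294, 2.15), Ctsd (2117 against 861, 1.30) and Igf2r (61.3 against 29.6, 1.05). Alternative and suppressive macrophage genes had a median of 0.13 (-0.05 to 0.22) over 28 members at the 95.4th percentile, with 8 higher, including the lipid receptor Trem2 (165 against 32.7, 2.33), and 6 lower. Glycolysis genes had a median of -0.33 (-0.39 to 0.02) over 17 members at the 0.28th percentile, with 3 lower, as in Hk2 (316 against 490.0, -0.63) and Slc2a1, a glucose transporter (158 against 237, -0.59).

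The lactate genes themselves differed less in CPM in monocyte or macrophage-like cells. Bsg was at 199 against 167 CPM (0.26, 0.05 to 0.47), Ldha at 495 against 426 (0.22, 0.08 to 0.35), Slc16a1 at 30.3 against 27.1 (0.16, -0.37 to 0.72, or 1.25 with the libraries clustered separately) and Slc16a3 at 166 against 171 (-0.05, -0.26 to 0.17), and the lactate list had a median of 0.07 (-0.08 to 0.20) over 14 members at the 80.3th percentile. After thinning, 33.6% (29.7 to 37.6) of treated and 25% (19.8 to 30.8) of control cells held a UMI of Ldha (61.1% and 54.7% unthinned), and 14.97% and 12.89% one of Slc16a3 (36.9% and 36.1%). Thinned hepatoma-like cells held a UMI of Slc16a3 in 2 of 1998 treated and 0 of 1847 control cells (up to 0.1995%). Bsg was seen in 15.7% (12.8 to 18.9) of treated and 12.1% (8.38 to 16.7) of control monocyte or macrophage-like cells (47.2% and 38.0% unthinned). Slc16a1 was seen in 4.13% (2.66 to 6.08) and 1.17% (0.242 to 3.39), the latter 3 of 256 cells (12% and 8.76% unthinned), against 2.95% and 3.03% of T or NK-like cells, which also express it. Cd274, which encodes PD-L1, was at 815 against 1261 CPM (-0.63), Mrc1, a mannose receptor, at 343 against 261 (0.39) and Nos2, the inducible nitric oxide synthase, at 192 against 403 (-1.07). In 270 treated and 51 control macrophage-like cells thinned to 1000 UMIs, Nos2 was seen in 10.0% (6.69 to 14.2) and 27.5% (15.9 to 41.7), and Cxcl9 in 8.52% (5.48 to 12.5) and 31.4% (19.1 to 45.9). Sub-cluster 5 held 29 of 307 treated and 26 of 60 control macrophage-like cells, so the make-up behind these shares differed. Its 10 leading genes within the class held Nos2 but no macrophage marker, while those against all cells included C1qa, C1qb and C1qc. Spp1 was seen in 38.1% (32.3 to 44.2) and 13.7% (5.70 to 26.3), and Arg1 in 41.9% (35.9 to 48.0) and 27.5% (15.9 to 41.7). Cd274 was seen in 40% (34.1 to 46.1) and 33.3% (20.8 to 47.9), the opposite direction to its CPM in the whole class, and Mrc1 in 23.7% (18.8 to 29.2) and 23.5% (12.8 to 37.5). Unthinned values were 16.6% and 50% for Nos2, 13.7% and 46.7% for Cxcl9, 55.7% and 33.3% for Spp1, 55.0% and 41.7% for Arg1, 67.4% and 68.3% for Cd274 and 47.9% and 43.3% for Mrc1. In thinned T or NK-like cells these genes were seen in 0.117% and 0.0278% for Nos2, 0.233% and 0.473% for Cxcl9, 1.40% and 0.612% for Spp1, 0.194% and 0.0278% for Arg1, 11.4% and 13.4% for Cd274 and 0.156% and 0.0278% for Mrc1. Median depths were 3750 UMIs in treated and 4804.5 in control macrophage-like cells.

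The largest monocyte or macrophage-like sub-cluster was number 0 in the control library (80 of 274) and number 1 in the treated library (148 of 650), and sub-clusters 1 and 4 came to 94.3% and 98.0% from the treated library, so they may be that library and not a type. With both left out, log2 ratios were 2.65 for Spp1, 1.58 for Arg1, 3.23 for Npy, 1.39 for Saa3, 1.008 for Cxcl1, 0.09 for Ctsk, -1.17 for Cxcl9, and -0.37, -0.46 and -0.14 for the interferon-gamma, MHC class II and MHC class I lists. With the libraries clustered separately Nos2 was at 0.88, Gbp2b at -1.103, Hk2 at -0.06 and the glycolysis list at 0.13. With mixed cells put back H2-Q6 was at -0.04, the lysosome list at 0.055 and the chemokine list at 0.41.

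Neutrophil-like cells of the treated library held more of genes for glycolysis and hypoxia and of tumour-associated neutrophil genes, and less of interferon-gamma response, MHC class I, granule and cell cycle genes. These values rest on 1402 treated and 169 control cells, and the median log2 ratio of all 3959 genes with at least 100 UMIs was -0.10. The genes with the greatest ratios were Jchain (75.5 against 1.91 CPM, log2 ratio 5.31, from 1 control UMI), the cysteine protease inhibitors Stfa1 (3.88) and Csta2 (3.66), the plasminogen activator inhibitor Serpinb2 (3.21) and Csf3, the neutrophil growth factor G-CSF (571 against 87.7, 2.70). They also included Saa3 (203 against 34.3, 2.56), Spp1 (4682 against 858, 2.45), the hypoxia-induced Fam162a (122 against 30.5), the transporter Abcc5 (1.90) and Cxcl3 (3444 against 1006, 1.78). Those with the smallest included Gbp4 (19.7 against 118, -2.58), Mki67 (42.5 against 183, -2.11), Tcf7l2 (-2.06), the class I gene H2-Q6 (83.0 against 334, -2.01), Colgalt1 (-1.98), the topoisomerase Top2a (-1.94), Clec12a (-1.93), Exoc4 (-1.92) and Zmpste24 (-1.86). Jchain was also among the leading genes of the B-like cluster. With 45 control and 31 treated cells, B-like cells were too few for the free RNA check, so free RNA could give the Jchain counts.

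Glycolysis genes had a median log2 ratio of 0.51 (0.32 to 0.59) over 17 members in neutrophil-like cells, at the 100th percentile, with 7 at least 1.5-fold higher and none lower, as in Pfkl (1.29), Pfkp (195 against 91.5 CPM, 1.09) and Pgk1 (259 against 137, 0.92). Hypoxia response genes had a median of 0.43 (0.29 to 0.67) over 19 members at the 100th percentile, with 8 higher and 2 lower, as in Ero1l (434 against 166, 1.39) and Bnip3 (0.98). Interferon-gamma response genes had a median of -0.83 (-0.98 to -0.69) over 28 members at the 0th percentile, with 19 lower and none higher, as in Tgtp1 (4.22 against 51.5, -3.61) and Gbp6 (-2.81). MHC class I genes had a median of -0.77 (-0.86 to -0.58) over 21 members at the 0th percentile, with 13 lower, as in Psmb9 (-1.43) and H2-Q7 (108 against 280.2, -1.38). Tumour neutrophil and suppressive myeloid genes had a median of 0.31 (0.22 to 0.43) over 30 members at the 100th percentile, with 12 higher and 5 lower, the latter including the acetate receptor Ffar2 (-1.69). Neutrophil maturation and granule genes had a median of -0.88 (-1.13 to -0.77) over 24 members at the 0th percentile, or -0.83 with the member at 0 in 1 library set to 3 counts, and 17 were at least 1.5-fold lower, as in Itgb2l (-2.07), Mmp8 (-1.37) and Retnlg (1047 against 2655, -1.34). Proliferation genes had a median of -2.06 (-2.40 to -1.802) over 14 members at the 0th percentile, with 13 lower, as in the mitotic motor Cenpe (4.46 against 49.6, -3.47).

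Bsg in neutrophil-like cells was at 130.2 against 109 CPM (0.26, -0.13 to 0.68), Slc16a3 at 210.4 against 173 (0.28, -0.03 to 0.61) and Ldha at 320.2 against 252 (0.35, 0.09 to 0.62). Cd274 was at 2687 against 2965 CPM (-0.14) and was seen in 81.5% (79.3 to 83.5) of treated and 79.7% (72.6 to 85.7) of control cells after thinning (90.9% and 91.1% unthinned), against 11.4% and 13.4% of T or NK-like cells. Arg2, a mitochondrial arginase, was at 933 against 707 CPM (0.40) and was seen in 55.0% (52.3 to 57.7) and 48.1% (40.1 to 56.2) of cells (79.9% and 73.4% unthinned), against 0.0389% and 0.139% of T or NK-like cells. Median depths were 2688.5 and 2616 UMIs in neutrophil-like cells.

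**Figure D5:**
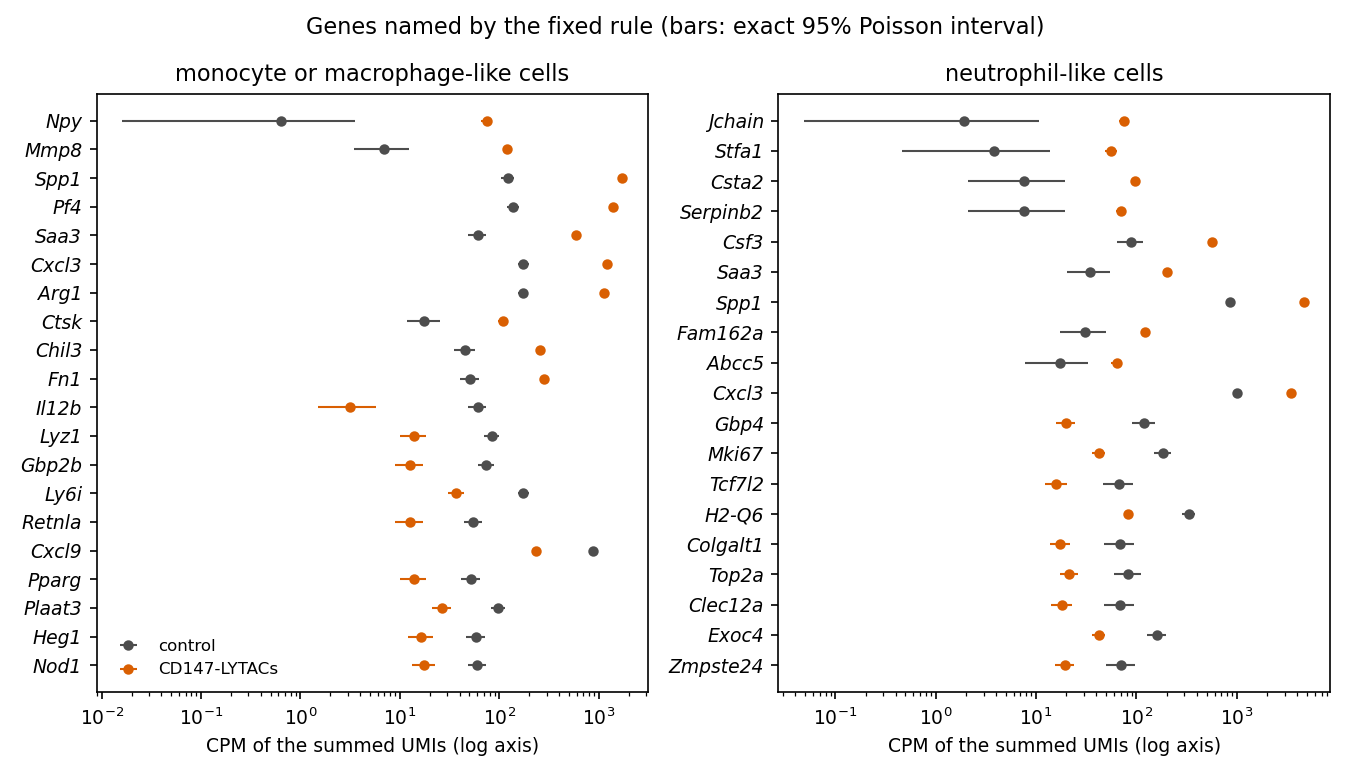
CPM of the summed UMIs (log axis) of genes named by the fixed rule and described in the text in monocyte or macrophage-like cells (left) and in neutrophil-like cells (right), in the control library (grey) and the CD147-LYTACs library (orange), with exact 95% Poisson intervals as lines. Spp1 stood at 122 and 1706 CPM on the left and at 858 and 4682 CPM on the right.

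Cluster 5 held 54.0% of treated and 21.3% of control neutrophil-like cells and came to 95.5% from the treated library, whereas cluster 8 held 44.0% and 72.2%. The class itself held 1402 treated and 169 control cells, so every cluster in it came mostly from the treated library. Leaving out cluster 5 takes away 757 treated and 36 control cells. Cluster 24, led by the granule genes Ngp, Camp and Ltf, held 28 of 1402 treated and 11 of 169 control cells, so the make-up of the class differed in cells rich in the granule genes. Without cluster 5, log2 ratios were 0.24 for the glycolysis list, 0.38 for Pfkl, 0.47 for Ero1l, 1.58 for Serpinb2, 1.35 for Saa3, -1.44 for Mki67 and -0.55 for the granule list. Without cells above 3 times the median UMIs, Saa3 was at 4.26 and Mki67 at -0.84. Without cluster 5 or without cells above 3 times the median UMIs, Jchain, a gene of antibody-secreting cells, turned to -1.25 or -1.15, and without those deep cells Top2a turned to 0.56 and the proliferation list to -0.32.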

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

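All thresholds used to weigh the explanations below were chosen only after the results were seen. A signal outside the compared cells was flagged because it stood above the control library: sub-clusters with markers of 2 lineages, which were left out of every comparison, held 7.32% of clustered cells in the treated library and 2.47% in the control library. Cells with both T cell and monocyte or macrophage markers numbered 467 treated and 99 control cells, a ratio of 4.72 (3.79 to 5.92). Random doublets at 1 rate would follow the product of both parent types, a ratio of 1.70. The observed ratio was 2.78 times that and its interval lies above it, but 2.78 stayed under the limit set for arguing against 1 rate. The interval covers counting error only, not differences between library preparations. Mixed cells left after doublet removal also need not follow the product at 1 rate, so 1 rate could not be judged. A higher doublet rate for every cell of the treated library remains open. Mixed T and hepatoma cells were also 1.76 times above their product, and mixed T and conventional dendritic cells 2.58 times. No sub-cluster was called mixed for T cell and neutrophil markers. In the treated library, however, neutrophil-like cells (1402) outnumbered monocyte or macrophage-like cells (650). Whether mixed T and neutrophil cells had been removed as doublets or had escaped the rule was not tested. The excess of T and monocyte or macrophage cells was 1.58 times that of T and hepatoma cells (0.989 to 2.52). These are cells left after 402 control and 535 treated barcodes had been removed as doublets. A single cell type with both programmes could not be judged. In CPM, 16 T cell and myeloid markers stood at a median of 49.6% of their level in unmixed cells. As CPM is a share of all UMIs, a single cell with both sets of transcripts would also show lower values. Treated mixed cells had a median of 7642 UMIs, against 6098 in T or NK-like and 3659 in monocyte or macrophage-like cells. T cells and myeloid cells held together through dissociation could not be told apart from the explanations still open with 1 treated library.

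The higher share of neutrophil-like cells in the treated library is the pattern most in need of a replicate. Loss through barcode filters or doublet removal does not account for it, because the lowest ratio of shares over 4 such settings was 6.93. Loss of low-RNA neutrophils from the control library before deposit could not be judged. The 10th percentile of UMIs per neutrophil-like cell in the control library was 0.897 times that in the treated library. That value covers named cells only, after the UMI filter and after low-UMI clusters had stayed unnamed. Unnamed cluster 19, led by Retnlg and Ccr3 with a median of 735 UMIs, held 37 control and 43 treated cells. Treatment and a difference between single tumours or dissociations could not be told apart with 1 library per group.

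Camk1d, Cdk8, Cmss1 and Lars2 were lower in the treated library in hepatoma-like cells, and a difference of the tumour cells alone is argued against. In 9 immune types and subsets, some of which overlap, 36 of 36 type and gene pairs had a log2 ratio below -0.2. Free RNA from the tumour cells is argued against as well, since the median level in immune types was 129% of that in hepatoma-like cells. A library-wide difference in RNA that includes ribosomal RNA fragments fits the values, because Gm42418, AY036118 and Gm26917 had a median log2 ratio of -0.51 over 10 types. These gene models overlap ribosomal RNA and were chosen after the result. Whether that difference was technical could not be told with 1 library per group. No biological explanation was tested for this pattern.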

How the results depend on the processing

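No paired analysis was possible because each group had 1 library. Filters, doublet removal, clustering, scaling and gene minimums were each varied in ways set beforehand, and 6 further variations were chosen after the data were seen. Values count as the same here when an alternative stayed inside the counting interval of the main value. They count as reversed only where the main interval excluded no difference, so other turns of direction are among the same or moved values. For cell shares this held for 68 of 85 alternative values, with 14 moved and 3 reversed. For gene lists it held for 493 of 567, with 70 moved and 4 reversed, and for genes for 1779 of 2142, with 352 moved and 11 reversed. For shares of cells with a UMI it held for 92 of 96, with 4 moved. Depth limits Slc16a3 in hepatoma-like cells and all values from few control myeloid cells. Under 100 cells in a library left no value for conventional dendritic-like cells in 6 settings, for monocyte-like cells in 3 and for NK-like cells in 1. The cause of the differences below was not tested.

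Ratios of shares, treated over control, were as follows. The neutrophil-like ratio stayed between 6.64 and 7.70 and the T or NK-like ratio between 0.613 and 0.649. The macrophage-like ratio was 1.17 with a looser filter, 1.56 with no doublet removal, 3.76 at Leiden resolution 0.5 and 1.29 at 2, and 3.45 with sub-clusters led by markers of another lineage unnamed. The monocyte-like ratio was 0.437 in that case, 1.23 with a stricter filter and 1.104 with sub-clusters named by fold against all cells. The monocyte or macrophage-like ratio was 2.602 with mixed cells put back. The CD8 T-like ratio was 1.04 at Leiden resolution 2 and 1.15 with the libraries clustered separately, where the NK-like ratio was 0.393.

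The log2 ratios below turned direction among those whose main interval excluded no difference. Turns of other log2 ratios are not listed, while Bsg and the lactate list, which moved, are added. With the libraries clustered separately, Gzmc in CD8 T-like cells was at -0.0883, Lag3 at 0.00599 and their proliferation list at -0.0196, that list in regulatory T-like cells at 0.51 and Nos2 in monocyte or macrophage-like cells at 0.88. Without cells above 3 times the median UMIs, Aldh1a2 in conventional dendritic-like cells was at 0.11, in regulatory T-like cells Ccl3 at 0.59 and the proliferation list at 0.0588, and in neutrophil-like cells Top2a at 0.56 and Jchain at -1.15. At a doublet rate of 1.6%, Ccl3 was at 0.60, Jchain at -0.96 and the naive and memory list in CD8 T-like cells at 0.0746. Jchain was at -1.03 with a stricter filter and at -1.25 without clusters over 90% from 1 library. In hepatoma-like cells, Bsg was at 0.0568 with median-of-ratios scaling and at 0.00315 as a mean over cells, where the lactate list was at 0.0462.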

Other observations

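The gene lists and naming rule were set beforehand, while S100a8 and S100a9 and the variation without cells above 3 times the median UMIs were chosen only after the results were seen. In regulatory T-like cells, 3 granzyme genes led the differences. Gzme was at 207 against 8.69 CPM (log2 ratio 4.57, 3.74 to 5.54), Gzmd at 158 against 18.8 (3.07) and Gzmb at 691 against 254 (1.45). The cytotoxic effector list had a median of 0.37 (0.25 to 0.59) over 24 members at the 100th percentile, with 10 at least 1.5-fold higher and 2 lower, or 0.41 with members at 0 in 1 library set to 3 counts. Ccl3, a chemokine, was at 58.1 against 175 CPM (-1.59) but at 1.73% of its level in another cell type, under the 20% limit set for free RNA. It was at 0.60 at a doublet rate of 1.6% and at 0.59 without cells above 3 times the median UMIs. The regulatory programme list lay at 0.17 (0.03 to 0.21) over 20 members, with the factor Ikzf4 at -0.75. Proliferation genes lay at -0.71 (-0.84 to -0.47) over 33 members, with 18 lower and 1 higher, but at 0.51 with the libraries clustered separately. These values rest on 109 treated and 152 control cells, in which Cd8a stood at 53.2 and Cd4 at 137.8 CPM, so CD8 T cells may be among them.

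Conventional dendritic-like cells of the treated library (102 against 130 control cells) differed in a few genes. Clec9a, known from cross-presenting dendritic cells, was at 22.7 against 114 CPM (-2.33) and Xcr1 at 30.03 against 87.6 (-1.54), while Cd200 (70.6 against 18.0, 1.97) and Il4i1 (135 against 45.1, 1.58) were higher. Clec9a, Xcr1, Cd200 and Il4i1 are also among the markers that name this class. No subsets were named within the class, so whether its make-up differed was not tested. Aldh1a2, the retinoic acid enzyme, was at 11.4 against 139.7 CPM (-3.62), but at 0.11 without cells above 3 times the median UMIs. The interferon-gamma list lay at -0.30 (-0.38 to -0.13) over 33 members with 8 lower, as in Iigp1 (-1.91), Serpina3g (-1.39) and Cxcl9 (215 against 502, -1.22). NK-like cells (133 against 109 control cells) held less of proliferation genes, with a median of -1.59 (-2.14 to -1.07) over 12 members and 10 lower, as in Mki67 (12.6 against 131 CPM, -3.37). With a stricter filter the list was at -0.58 and Mki67 at -1.12, and without cells above 3 times the median UMIs the list was at -0.51. Their cytotoxic list lay at -0.13 over 22 members, with Gzmc at 504 against 923 CPM (-0.87).

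S100a8 and S100a9, neutrophil genes picked after the data were seen, were at 4.53 and 5.87 CPM in treated hepatoma-like cells against 0.793 and 0.653 in control ones. In T or NK-like cells they were at 5.67 and 9.16 against 1.67 and 2.08 CPM.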
